A study of Homo sapiens with 3 samples.

How the data were processed

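Total RNA of human aortic endothelial cells was labelled with biotin and hybridised to Illumina expression arrays. The labels give 1 sample for each of 3 groups: control medium, OxPAPC and 15dPGJ2. They state that duplicate wells were treated, and the deposited table of raw values states that each group value rests on 2 arrays. Nothing in the sources used here says that the 2 arrays of a group came from separate wells, so p-values and standard errors measure only the spread between these arrays, which may be technical. A further oxidised phospholipid named in the labels has no sample among these 3 groups, so it was not analysed here.

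Per the file headers, the deposited raw table gives for each probe and group the mean intensity of 2 arrays on a linear scale, the SD of that intensity over the 2 arrays, the number of arrays and a detection p-value. Per the submitters' processing notes the authors used GenomeStudio, with its version not given in the sources used here. Its detection p-value compares a probe with the negative control beads. The second deposited table holds the authors' processed intensity per probe and sample. From its values it is on a linear scale and background-subtracted, with 13221, 13342 and 13251 values below 0 for control, OxPAPC and 15dPGJ2, and it is normalized to nearly equal medians of 20.35, 20.2 and 20.5. The method of that normalization is not given in the sources used here. Across probes the authors' processed intensity and the raw intensity had the same order in each group, with Spearman's rho of 0.99998, 0.99997 and 0.99999. After each probe's mean over the groups was removed, each authors' column correlated with the raw column of the same name at r of 0.9705, 0.953 and 0.9461. Correlations with the other columns were negative, a sign that removing the mean itself brings about.

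The tables hold 47320 probes. The platform annotation gave 1 gene for 30113 probes, several for 8 and no name for 17199. Gene symbols were updated through the gene identifier, which was found in the RefSeq table for 30074 of the 1-gene probes. The 144 probes of sex-linked genes specific to individuals were left out. The remaining probes named 19951 genes, each represented by the probe with the highest mean normalized value. Where a named gene passed 2-fold and another of its detected probes did not, the text gives that probe. Smaller differences between probes are not given.

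The raw intensities of the 3 groups were background-corrected with normexp using the detection p-values, given an offset of 16, quantile-normalized together and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. Genes were counted in a comparison when detected at p under 0.01 in at least 1 of its 2 groups. The rule set before the data were examined was a difference of at least 2-fold with no p-value, because only 1 sample per group was foreseen. The tables turned out to hold an SD over 2 arrays as well. The values of the 2 arrays were therefore rebuilt on the log2 scale as the mean plus and minus the deviation that the deposited SD corresponds to, and were fitted with limma (lmFit and eBayes with an intensity trend, 3 groups sharing 1 residual variance) with Benjamini-Hochberg adjustment. This step was chosen after the data were seen. The fit had 3 residual degrees of freedom and, with the variance shared over genes, 37.61, 34.89 and 39.08 in all for the 3 comparisons. In the text a gene rose or fell when it met both the 2-fold rule and a limma adjusted p under 0.05, and ± gives limma's standard error of the log2 difference. The SD includes brightness differences between the 2 arrays of a group, since only their mean could be normalized.

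A gene not detected in its dimmer group has only a bound. It is given as at least N-fold, from the brighter group's value against the higher of the lowest normalized value detected in the dimmer group and the gene's own value there. The fold changes of genes near that level depend on the offset.

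Named genes follow a rule set before the data were examined. It takes the 12 largest rises and falls for each treatment against control, the 8 largest each way between the treatments, up to 4 detected members with the largest difference from each of 26 gene lists, 14 genes named in advance, and the reference genes. Genes named in advance without a named probe, such as OSGIN1, have no value. Any gene outside this rule is said to have been chosen after its values were seen. The 26 lists hold 572 genes of stress responses, lipid synthesis, inflammation, endothelial identity, signalling, cell cycle, housekeeping and other cell types, and were fixed from textbook knowledge. For lists with at least 4 detected members, the median log2 difference was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins (medians by matrixStats 1.5.0), as a description of these arrays. A list is said to stand apart when its median lay at or above percentile 97.5 or at or below percentile 2.5. Counts adjusted over the list alone were also made. Set tests that estimate the correlation between genes could not be run, because which array is which is unknown.

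The treatments share 1 control group. Overlap and correlation were set beside 100 simulations of unchanged arrays that share a control, with noise taken from the median absolute deviation of the observed differences at each intensity, and beside the overlap of independent lists. The control could not be split into parts of at least 2 separate arrays.

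The steps were tested on simulated data before use. In a simulated OxPAPC minus control comparison with 10258 genes in the step and 50 genes changed by each of 2-, 3-, 4- and 8-fold, 44%, 94%, 98% and 100% passed the 2-fold rule, and 26%, 74%, 92% and 92% also passed the limma rule. Among the unchanged genes 92 passed the 2-fold rule and 1 passed both rules. The changed genes were drawn from genes detected in all 3 groups and above background, and the noise came only from the SD over arrays. These rates therefore do not cover genes undetected in a group, or differences between wells or cultures.

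Alternatives changed 1 choice at a time: no background correction, an offset of 50, median scaling, other detection filters, the mean over all detected probes of a gene, and thresholds of 1.5-fold and 3-fold. A further alternative, the authors' processed intensities (values under 16 set to 16), changed background correction, normalization and offset together. The limma rule and a rule that every pairing of the arrays of both groups reach 2-fold were added after the data were seen.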

Results

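Gene expression was measured on Illumina arrays in human aortic endothelial cells, the primary cells that line the inside of the aorta. The cells were grown with 20% serum and then held for 4 h in medium with 1% serum alone (control), with 64 µM OxPAPC or with 5 µM 15dPGJ2. OxPAPC is a mixture of oxidation products of an arachidonate-containing phosphatidylcholine, as found in minimally oxidised lipoprotein. 15dPGJ2 is a cyclopentenone prostaglandin that reacts with cysteine thiols and is also a ligand of the nuclear receptor PPARγ. The series concerns the interaction of OxPAPC with cysteines in endothelial function, and the 15dPGJ2 group allows the genes changed by OxPAPC to be set beside those changed by a thiol-reactive lipid. Doses differed between the compounds and the time did not.

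Each group was 1 sample with values averaged over 2 arrays. The mean raw intensity was 613 in control, 658 in OxPAPC and 553 in 15dPGJ2. In the same order, 15583, 15096 and 15297 of the 47320 probes were detected, and the median SD of detected probes over the 2 arrays was 6.72%, 8.41% and 6.52% of the mean. On the normalized log2 scale the median SD was 0.133, 0.162 and 0.133. With 1 sample per group, the standard errors and adjusted p-values below measure only the spread between the 2 arrays, which may be technical. They do not cover differences between wells or cultures. All 11 measured reference genes stayed under 2-fold in every comparison, for example ACTB (0.17 ± 0.12 after OxPAPC and 0.06 ± 0.12 after 15dPGJ2), GAPDH (0.15 ± 0.12 and 0.15 ± 0.12) and B2M (−0.19 ± 0.12 and −0.07 ± 0.12). The 28 detected cytosolic ribosomal protein genes had a median log2 difference of −0.01 after OxPAPC and 0.02 after 15dPGJ2, the latter 0.21 with median scaling, and 0 of them reached 2-fold.

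The question of the OxPAPC comparison was which genes the oxidised phospholipid changed against medium alone. The cytosolic heat shock genes held the largest rises. HSPA1A and HSPA1B, which encode the inducible HSP70 chaperone, rose 23.5-fold (log2 difference 4.55 ± 0.14) and 21.5-fold (4.43 ± 0.13), and the co-chaperone gene DNAJB1 rose 10.9-fold (3.44 ± 0.15). ATF3, a stress-induced transcription factor, rose 17.0-fold (4.09 ± 0.14), and HMOX1, the inducible haem oxygenase, rose 4.16-fold (2.06 ± 0.12). CYP26B1, which clears retinoic acid, fell by 4.80 ± 0.20 on the log2 scale, and the chemokine gene CCL20 fell by 4.02 ± 0.20. The limma adjusted p of these genes ran from 4.49e-26 for HSPA1B to 2.67e-16 for HMOX1.

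Among the other large rises after OxPAPC, HSPA6 was at least 30.5-fold higher, its relative HSPA7 at least 7.43-fold, the microRNA gene MIR21 at least 10.6-fold, and the immediate early genes KLF4 and FOS at least 4.97-fold and 3.73-fold, all of them not detected in control. EID3 rose 10.3-fold, the calcineurin regulator RCAN1 9.06-fold and the arsenite-inducible ZFAND2A 8.45-fold. The gene pairs HSPA1A and HSPA1B, and HSPA6 and HSPA7, are near-identical copies, so the share of each within its pair is uncertain. Large falls were measured for PDGFB, the B chain of platelet-derived growth factor (−3.46 ± 0.23), the immune-associated GTPase GIMAP7 (−3.45 ± 0.16), the thioredoxin-binding protein TXNIP (−3.23 ± 0.21), the phosphodiesterase PDE4B (−3.17 ± 0.23) and GJA4, which encodes an arterial gap junction protein (−2.98 ± 0.24). FAM110D, SH2D3C, ZNF792 and TSPAN1 were at least 6.55-, 6.16-, 4.42- and 6.70-fold lower and not detected after OxPAPC. In all, 279 of 9964 detected genes were at least 2-fold higher and 373 at least 2-fold lower, of which 257 rose and 338 fell by limma. With the genes not detected in 1 group set at their bounds, 218 were at least 2-fold higher and 291 lower. Without background correction, which shrinks the differences of dim genes, the counts were 108 and 112.

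**Figure D1:**
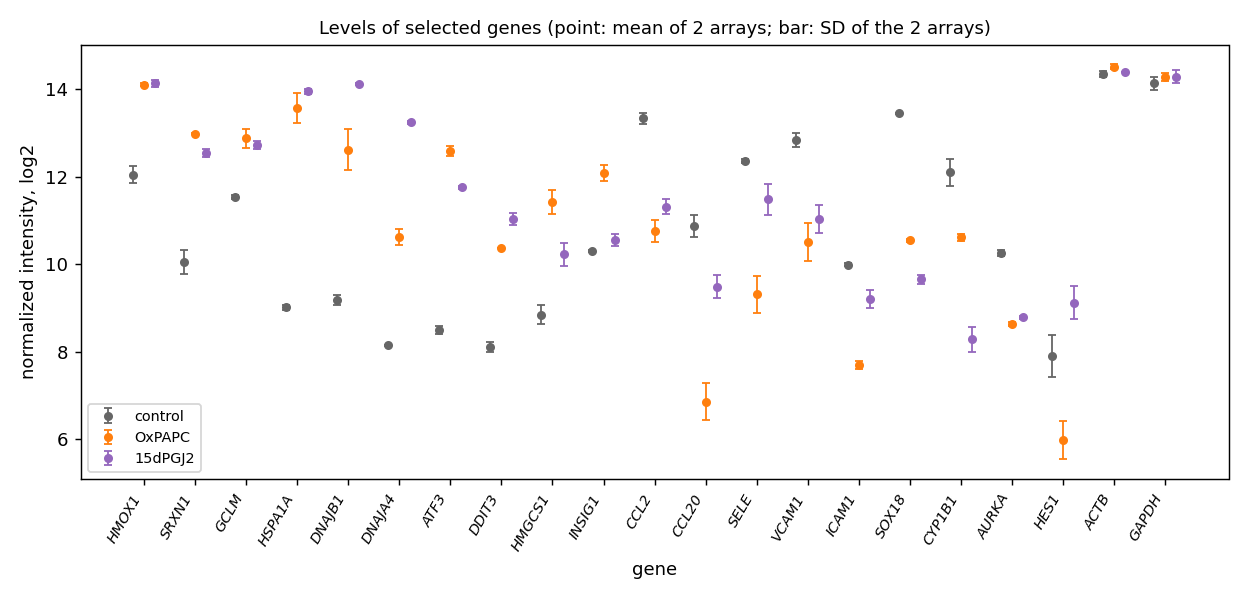
Normalized log2 intensity (vertical axis) of 21 genes (horizontal axis) in control, OxPAPC and 15dPGJ2, with points for the mean of 2 arrays and bars for their SD. HMOX1 rose to similar levels after both compounds (14.1 in each, against 12.05 in control), DNAJA4 was highest after 15dPGJ2, INSIG1 was highest after OxPAPC, and HES1 lay below control after OxPAPC and above it after 15dPGJ2.

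Of the 24 gene lists tested 7 stood above and 6 below random lists after OxPAPC. Of 27 detected cytosolic heat shock genes 14 rose and 0 fell, with a median log2 difference of 1.04 that lay above all 10000 random lists (percentile 100), and at any size 25 were higher by limma both over all genes and adjusted over the list alone. Of 34 detected genes of the NRF2 and glutathione response 7 rose and 0 fell (median 0.46, percentile 100). At any size 17 were higher and 1 lower over all genes, and 20 and 2 adjusted over the list alone. Among them SRXN1, which repairs oxidised peroxiredoxins, rose 7.62-fold (2.93 ± 0.14), the cystine transporter SLC7A11 2.95-fold (1.56 ± 0.16) and the glutathione synthesis gene GCLM 2.54-fold (1.34 ± 0.13). AKR1B10 was at least 1.58-fold higher, and NQO1, also in this list, differed by 0.06 ± 0.12. Of 32 detected ATF4 amino acid and stress response genes 7 rose and 0 fell (median 0.46, percentile 100, 15 higher and 1 lower adjusted over the list alone), with DDIT3 at 4.82-fold (2.27 ± 0.16), the phosphatase subunit PPP1R15A at 3.09-fold (1.63 ± 0.13) and the glutathione-degrading CHAC1 at least 3.36-fold. In contrast, 1 of 20 detected endoplasmic reticulum chaperone genes rose, DNAJB9 (2.06 ± 0.15), while XBP1 differed by 0.64 ± 0.14 (median 0.06, percentile 89.8, 2 higher and 1 lower adjusted over the list alone).

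The sterol synthesis and immediate early lists also stood above random lists after OxPAPC. Of 19 detected sterol synthesis and uptake genes 6 rose and 0 fell (median 0.49, percentile 100, 10 higher adjusted over the list alone). HMGCS1, an early enzyme of cholesterol synthesis, rose 5.98-fold (2.58 ± 0.17), INSIG1, which holds back sterol-regulated transcription factors, 3.42-fold (1.77 ± 0.14), the squalene epoxidase gene SQLE 2.495-fold (1.32 ± 0.15) and MSMO1 3.62-fold (1.86 ± 0.16), although the 3 detected MSMO1 probes ranged from −0.11 to 2.35. Of 25 detected immediate early genes 8 rose and 0 fell (median 0.48, percentile 100, 15 higher and 3 lower adjusted over the list alone), among them FOSB at least 3.96-fold. In the hypoxia and glycolysis list 1 of 15 rose, the glucose transporter SLC2A1 (1.52 ± 0.19), and VEGFA differed by 0.50 ± 0.28 (median 0.35, percentile 99.99, 4 higher and 1 lower adjusted over the list alone). Of 27 proteasome subunit genes 0 reached 2-fold, and their median of 0.08 lay at percentile 98.22, with PSMD11 at 0.80 ± 0.23 (5 higher adjusted over the list alone).

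The inflammatory and interferon lists stood below random lists after OxPAPC, and the adhesion list did not stand apart. Of 22 detected inflammatory cytokine and NF-κB target genes 6 fell and 1 rose (median −0.62, percentile 0, and −0.41 with undetected values at their bounds), and adjusted over the list alone 10 were lower and 3 higher. CCL2, the monocyte chemoattractant, fell by 2.58 ± 0.14, TNFAIP2 and CX3CL1 were at least 3.08-fold and 2.93-fold lower, IL6 differed by −0.76 ± 0.16 and CXCL8 by 0.52 ± 0.12, both under 2-fold, with a second CXCL8 probe at 1.05. Of 14 detected leukocyte adhesion genes 3 fell, 0 rose and 11 were under 2-fold. The 3 were E-selectin (SELE, −3.04 ± 0.16, with its second probe at −0.56), VCAM1 (−2.33 ± 0.16) and ICAM1 (−2.30 ± 0.19), while SELP differed by 0.30 ± 0.20 (median −0.12, percentile 9.56, 3 lower adjusted over the list alone). Of 23 interferon-stimulated genes 4 fell and 1 rose (median −0.67, percentile 0, and −0.50 at the bounds; 12 lower and 2 higher adjusted over the list alone). IFIT2 fell by 2.48 ± 0.26, IFIT1 by 2.12 ± 0.32 and the transcription factor IRF1 by 1.34 ± 0.19. OAS1 was at least 1.98-fold higher by its brightest probe, but its 3 probes ran from −1.35 to 1.19 and their mean was −0.37.

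The endothelial identity, BMP and TGF-β target and mitotic lists also stood below random lists after OxPAPC. Of 30 detected endothelial identity genes 5 fell, 2 rose and 23 were under 2-fold (median −0.27, percentile 0, 12 lower and 2 higher adjusted over the list alone). The transcription factors SOX18 and SOX7 fell by 2.90 ± 0.13 and 2.28 ± 0.18 and the secreted factor EGFL7 by 2.27 ± 0.19, while KLF4 rose (at least 4.97-fold). Of 14 BMP and TGF-β target genes 4 fell and 0 rose (median −0.39, percentile 0.06, and −0.22 at the bounds; 7 lower and 3 higher adjusted over the list alone), with BMP4 at −2.66 ± 0.27, ID1 at −1.65 ± 0.20, ID3 at −1.30 ± 0.14 and SMAD6 at −1.16 ± 0.26. Of 23 mitotic genes 8 fell and 0 rose (median −0.83, percentile 0, 20 lower adjusted over the list alone). The kinase genes AURKA and TTK fell by 1.62 ± 0.18 and 1.15 ± 0.24, as did the centromere histone CENPA (−1.50 ± 0.23) and KIF23 (−1.25 ± 0.22), with a second KIF23 probe at 0.11. Of 20 S phase genes only E2F1 rose (1.33 ± 0.30) and 0 fell (median −0.05, percentile 41.9, 3 higher and 1 lower adjusted over the list alone). In the metallothionein list, of 8 genes the zinc exporter SLC30A1 fell (−1.10 ± 0.26, with a second probe at −0.80), MT1E differed by −0.79 ± 0.14, and the median of −0.76 lay at percentile 0.02 (5 lower adjusted over the list alone).

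The remaining lists moved little or both ways after OxPAPC. Of 10 PPAR target genes ANGPTL4 (−2.82 ± 0.20) and PDK4 (−2.68 ± 0.22) fell and PPARG itself rose (1.09 ± 0.22; median −0.21, percentile 4.6, 3 lower and 1 higher adjusted over the list alone). Of 12 haemostasis genes the coagulation initiator F3 rose 6.03-fold (2.59 ± 0.26) and PLAU fell by 1.01 ± 0.18 (median −0.07, percentile 30.1, 1 higher and 2 lower adjusted over the list alone). Of 11 Notch signalling genes HES1 fell, at least 3.13-fold (median −0.19, percentile 17.5, 3 lower and 1 higher adjusted over the list alone), and of 16 p53 target genes SESN1 fell (−1.41 ± 0.23; median 0.05, percentile 84.7, 4 higher and 3 lower adjusted over the list alone). Markers of other cells were few: 0 of 5 smooth muscle and fibroblast, 0 of 4 leukocyte and 0 of 3 epithelial markers detected reached 2-fold, and of 2 lymphatic markers RELN was at least 1.38-fold higher while LYVE1 differed by −0.33 ± 0.15. Without background correction AKR1B10, CHAC1, HES1, SMAD6, PPARG, PLAU, SLC30A1, E2F1, KIF23, TTK, OAS1 and RELN were under 2-fold.

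The 15dPGJ2 comparison asked the same of the prostaglandin. HSPA6, a strictly inducible HSP70 gene, was at least 276-fold higher than in control, where it was not detected, and HSPA7 at least 175-fold. DNAJA4 rose 34.2-fold (5.09 ± 0.14), DNAJB1 30.6-fold (4.94 ± 0.15), HSPA1A 30.5-fold (4.93 ± 0.14) and HSPA1B 27.7-fold (4.79 ± 0.13). HMOX1 rose 4.24-fold (2.08 ± 0.12) and ATF3 9.54-fold (3.25 ± 0.14). Among the largest falls were 3 cytochrome P450 genes. CYP1A1 was at least 19.3-fold lower and not detected, CYP26B1 fell by 3.96 ± 0.20 and CYP1B1 by 3.81 ± 0.16. The limma adjusted p of these genes ran from 4.52e-30 for HSPA6 to 5.79e-16 for HMOX1.

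Further large rises after 15dPGJ2 were those of DHDH (at least 19.9-fold), HSPA1L (at least 16.3-fold), FOSB (at least 12.3-fold), EID3 (16.9-fold) and RNVU1-18 and RNVU1-7 (13.5-fold and 13.1-fold), which belong to the U1 small nuclear RNA family of near-identical copies. The transcription factor SOX18 (−3.79 ± 0.13), DEPP1 (−4.15 ± 0.16), HPS6 (−3.42 ± 0.20) and PDGFB (−3.28 ± 0.23) fell. HTR2B, a serotonin receptor gene, was at least 9.77-fold lower, INKA1 at least 7.43-fold, RPUSD2 at least 7.27-fold, TSPAN1 at least 7.05-fold and the small nucleolar RNA SNORA25 at least 4.48-fold, each not detected after 15dPGJ2. In all, 421 of 10101 detected genes were at least 2-fold higher and 506 lower, of which 399 rose and 481 fell by limma, and 328 and 377 reached 2-fold with undetected values at their bounds. Without background correction 182 and 134 reached 2-fold. With median scaling in place of quantile normalization 55.7% of the genes past 2-fold were higher, against 45.4% here.

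Of the 24 lists 11, the reference genes among them, stood above and 5 below random lists after 15dPGJ2. Of 27 detected heat shock genes 21 rose and 0 fell (median 1.97, percentile 100, 26 higher at any size both over all genes and adjusted over the list alone). Of 32 ATF4 response genes 9 rose and 0 fell (median 0.54, percentile 100, 18 higher and 1 lower adjusted over the list alone). DDIT3 rose 7.61-fold (2.93 ± 0.16), SESN2 4.54-fold (2.18 ± 0.25) and CHAC1 at least 4.70-fold. Of 34 NRF2 and glutathione genes 6 rose and 0 fell (median 0.39, percentile 100, 14 higher and 1 lower adjusted over the list alone), with SRXN1 at 5.64-fold (2.495 ± 0.14), SLC7A11 at 3.49-fold (1.81 ± 0.16), GCLM at 2.29-fold (1.19 ± 0.13) and AKR1B10 at least 1.97-fold. NQO1 differed by −0.24 ± 0.12. Of 20 endoplasmic reticulum chaperone genes 2 rose, DNAJB9 (2.58 ± 0.15) and HSPA5, the main chaperone of that compartment (1.33 ± 0.14), and the median was 0.24 (percentile 100, 9 higher and 1 lower adjusted over the list alone). The 27 proteasome genes had a median of 0.21 (percentile 100) with 0 past 2-fold and 7 higher adjusted over the list alone, PSMD11 at 0.92 ± 0.23. The median of the 11 reference genes, 0.12, also lay at the upper percentile limit.

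**Figure D2:**
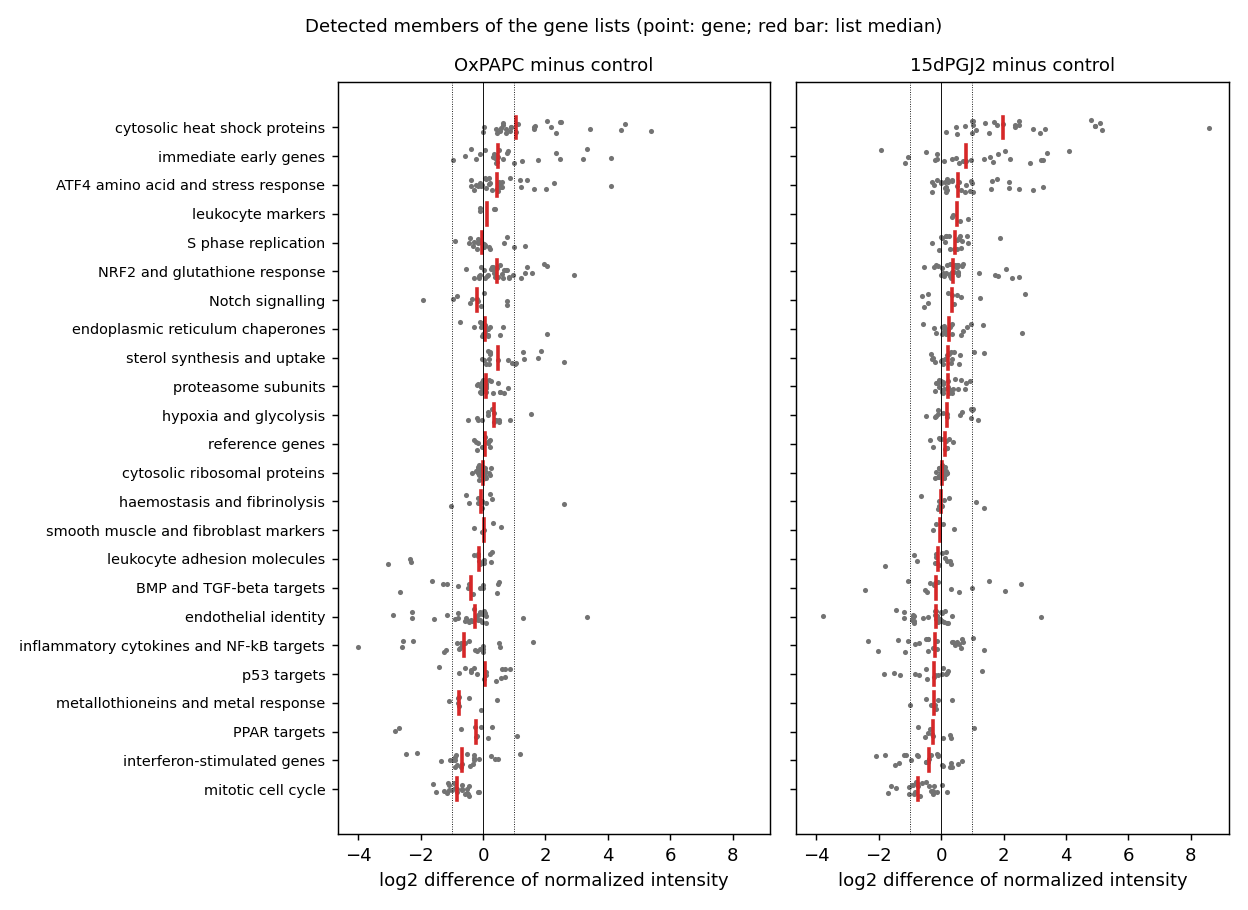
Log2 difference of normalized intensity (horizontal axes) of the detected members of each gene list (vertical axis) after OxPAPC (left) and 15dPGJ2 (right), each against control, with a point per gene, red bars at list medians and dotted lines at 2-fold. Heat shock genes have the highest median in both panels (1.04 and 1.97) and mitotic genes the lowest (−0.83 and −0.73).

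Immediate early and signalling genes moved in both directions after 15dPGJ2. Of 25 immediate early genes 11 rose and 3 fell (median 0.80, percentile 100, 17 higher and 4 lower adjusted over the list alone), and FOS and KLF4 were at least 4.28-fold and 4.56-fold higher. Of 11 Notch genes HEY1 (2.67 ± 0.26, with a second probe at 0.44) and HES1 (1.23 ± 0.28) rose and 0 fell (median 0.34, percentile 98.29, and 0.21 at the bounds; 3 higher and 2 lower adjusted over the list alone). Of 14 BMP and TGF-β targets 3 rose and 2 fell (median −0.15, percentile 14.0, 5 higher and 5 lower adjusted over the list alone). ID2 rose 5.92-fold (2.57 ± 0.20), the inhibitory SMAD7 4.11-fold (2.04 ± 0.32) and BAMBI 2.88-fold (1.53 ± 0.16), and BMP4 fell by 2.43 ± 0.28. Of 18 sterol genes HMGCS1 (1.38 ± 0.17) and PMVK (1.06 ± 0.18) rose, and INSIG1 differed by 0.25 ± 0.14 (median 0.22, percentile 99.1, 3 higher adjusted over the list alone). Of 15 hypoxia and glycolysis genes SLC2A3 (1.17 ± 0.14) and P4HA1 (1.01 ± 0.17) rose, with VEGFA at 0.96 ± 0.28 (median 0.20, percentile 99.3, 7 higher and 1 lower adjusted over the list alone).

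The inflammatory, interferon and endothelial lists stood below random lists after 15dPGJ2, and the adhesion list did not stand apart. Of 24 inflammatory genes 5 fell and 1 rose (median −0.21, percentile 1.76, and −0.14 at the bounds; 5 lower and 7 higher adjusted over the list alone). CCL2 fell by 2.03 ± 0.14 and CCL20 by 1.39 ± 0.20, CX3CL1 was at least 3.09-fold lower, and PTGS2, the inducible cyclooxygenase, rose 2.60-fold (1.38 ± 0.13). IL6 differed by 0.38 ± 0.16 and CXCL8 by 0.58 ± 0.12. VCAM1 was the adhesion gene of 14 that fell (−1.81 ± 0.16), with SELE at −0.87 ± 0.16 and ICAM1 at −0.79 ± 0.19, both under 2-fold (median −0.11, percentile 14.1, 3 lower adjusted over the list alone). Of 24 interferon-stimulated genes 6 fell and 0 rose (median −0.40, percentile 0.06, 9 lower and 1 higher adjusted over the list alone), including IFIT1 (−2.10 ± 0.32), IFIT2 (−1.80 ± 0.26), IFIH1 (−1.49 ± 0.25) and RIGI (−1.34 ± 0.26). Of 30 endothelial identity genes 4 fell and 1 rose (median −0.17, percentile 1.31, 10 lower and 1 higher adjusted over the list alone), among them SOX7 (−1.45 ± 0.18) and EGFL7 (−1.20 ± 0.19, with a second probe at −0.66). With median scaling the endothelial median was −0.04 and no longer stood apart, and the inflammatory median did not stand apart in 4 alternatives, for example −0.15 without background correction.

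Of 23 mitotic genes 5 fell and 0 rose after 15dPGJ2 (median −0.73, percentile 0, 14 lower adjusted over the list alone), with CENPA at −1.69 ± 0.23, TTK at −1.60 ± 0.24, AURKA at −1.46 ± 0.18 and ASPM at −1.05 ± 0.16. Of 20 S phase genes MCM10 rose, at least 3.43-fold, and the median of 0.45 lay at percentile 100 (9 higher adjusted over the list alone), with CDT1 at 0.82 ± 0.26 and RRM2 at 0.67 ± 0.24. Of 16 p53 targets SESN1 (−1.84 ± 0.23), PLK2 (−1.50 ± 0.19) and PHLDA3 (−1.32 ± 0.21) fell and SERTAD1 rose (1.32 ± 0.15; median −0.22, percentile 1.87, 6 lower and 1 higher adjusted over the list alone). Of 10 PPAR targets PPARG rose (1.06 ± 0.22) and 0 fell, with PDK4 at −0.76 ± 0.22 and the fatty acid carrier FABP4 at −0.42 ± 0.13 (median −0.27, percentile 3.96, 3 lower and 1 higher adjusted over the list alone). Of 12 haemostasis genes F3 (1.36 ± 0.26) and PLAUR (1.10 ± 0.17, its 3 probes from 0.48 to 1.48) rose (median −0.01, percentile 60.8, 2 higher and 1 lower adjusted over the list alone), and of 8 metallothionein genes MT1M was at least 1.94-fold lower (median −0.24, percentile 6.47, 2 lower adjusted over the list alone). Of markers of other cells, 0 of 4 smooth muscle, 0 of 4 leukocyte (median 0.50, percentile 97.2, CD79A at 0.85 ± 0.36) and 0 of 3 epithelial markers reached 2-fold, while the lymphatic regulator PROX1 was at least 2.72-fold higher and LYVE1 differed by −0.14 ± 0.15. Without background correction PMVK, HES1, PPARG, F3, PLAUR, MT1M, PHLDA3, MCM10, ASPM, IFIH1, RIGI, P4HA1 and PROX1 were under 2-fold.

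The responses to the compounds were then compared gene by gene. Among 9780 genes detected for both, 157 were at least 2-fold higher after both, 192 at least 2-fold lower after both and 1, HES1, moved past 2-fold in opposite directions. Genes higher after both included HSPA1A, DNAJB1, ATF3, SRXN1, HMOX1, GCLM and DDIT3, and genes lower after both included CYP26B1, PDGFB, SOX18, GIMAP7, CCL2, VCAM1, BMP4 and AURKA. Among these 9780 genes, the shared genes made up 57.0% of the 239 higher and 373 lower after OxPAPC. They made up 41.5% of the 335 higher and 506 lower after 15dPGJ2. Genes detected for 1 comparison only lie outside these shares. Over all genes past 2-fold (279 higher and 373 lower after OxPAPC, 421 and 506 after 15dPGJ2) the shares would be smaller. Independent lists of the same sizes would share 8.19 higher and 19.3 lower genes and place 25.1 in opposite directions. Simulated unchanged arrays with a common control, in which about 197 genes passed 2-fold per treatment, shared 18.2 higher (at most 27) and 18.3 lower genes (at most 29) and placed 0.06 (at most 1) in opposite directions, so a count of 1 is also reached without any change. Across genes, which are not independent replicates, the log2 differences correlated at r = 0.699 and rho = 0.612, against a simulated r of 0.501. Their covariance was 0.236 against 0.0777 in the simulations, a difference of 0.159. The control could not be split, so part of the excess may come from the shared control.

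**Figure D3:**
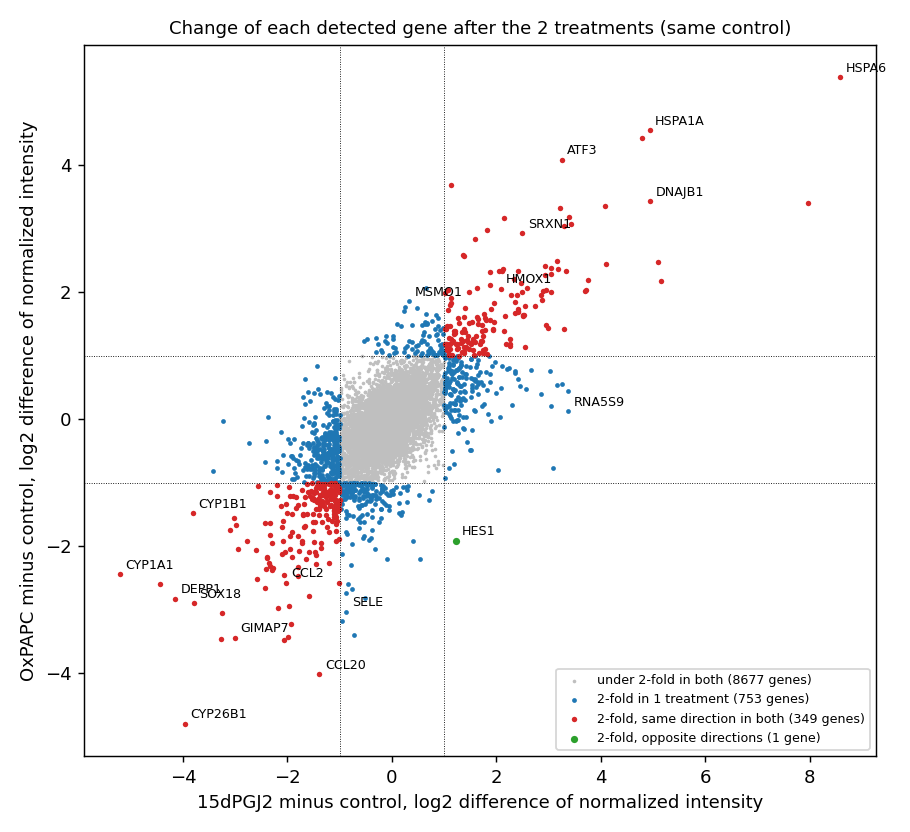
Log2 difference of normalized intensity against control after 15dPGJ2 (horizontal axis) and OxPAPC (vertical axis) for 9780 genes, with dotted lines at 2-fold and selected genes named. The 349 genes past 2-fold in the same direction (red) run along the diagonal, 753 genes passed 2-fold after 1 compound (blue), and HES1 (green) passed it in opposite directions.

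Set directly against 15dPGJ2 at their different doses, OxPAPC gave lower heat shock and higher sterol synthesis expression. Of 27 heat shock genes 8 were lower and 0 higher after OxPAPC (median −0.68, percentile 0, 22 lower adjusted over the list alone), with HSPA6 at −3.18 ± 0.17, HSPA1L at −2.97 ± 0.27, DNAJA4 at −2.62 ± 0.14 and the co-chaperone FKBP4 at −1.61 ± 0.16. Of 19 sterol genes 5 were higher and 0 lower (median 0.46, percentile 99.99, 8 higher and 1 lower adjusted over the list alone), with IDI1 at 1.58 ± 0.21, MSMO1 at 1.53 ± 0.16 (its probes from −0.21 to 2.22), INSIG1 at 1.52 ± 0.14 and SQLE at 1.30 ± 0.15. The limma adjusted p of these 8 genes ran from 1.40e-17 for HSPA6 to 2.26e-07 for IDI1. HMOX1 differed by −0.02 (95% confidence interval −0.27 to 0.22), GCLM by 0.15 (−0.11 to 0.41) and CXCL8 by −0.06 (−0.30 to 0.18). The intervals leave room for small differences in either direction and cover only the spread between arrays. After OxPAPC and 15dPGJ2, HMOX1 (14.1 in each) and CXCL8 (14.2 and 14.3) lay near ACTB (14.5 and 14.4) on the log2 scale. Whether differences are compressed at such bright levels was not tested. Of 34 NRF2 and glutathione genes 0 differed by 2-fold (median 0.08, percentile 94.9, 3 higher adjusted over the list alone).

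Other genes separated the compounds. MIR21 (2.56 ± 0.27), CYP1B1 (2.33 ± 0.16), HPS6 (2.60 ± 0.20) and SNORA61 (2.29 ± 0.21) were higher after OxPAPC, and CYP1A1, SNORA25, CREBZF and CTTNBP2NL at least 3.55-, 4.37-, 3.29- and 2.95-fold higher. DHDH was at least 18.6-fold lower, HES1 at least 7.32-fold and the vault RNA VTRNA2-1 at least 5.46-fold, and HSPA7 (−4.56 ± 0.19), the glycogen regulator PPP1R3C (−3.86 ± 0.25) and the ribosomal 5S RNA gene RNA5S9 (−3.25 ± 0.17) were lower. Of 22 inflammatory genes 5 were lower and 0 higher (median −0.40, percentile 0, but −0.04 with undetected values at their bounds; 9 lower and 1 higher adjusted over the list alone), with CCL20 at −2.63 ± 0.20, TNFAIP3 at −1.71 ± 0.27, IL1A at −1.43 ± 0.29 and IL6 at −1.14 ± 0.16. SELE (−2.17 ± 0.16) and ICAM1 (−1.51 ± 0.19) were the 2 of 14 adhesion genes that were lower, while CCL2 and VCAM1 differed by −0.55 ± 0.14 and −0.52 ± 0.16 (adhesion median −0.07, percentile 9.75, 3 lower adjusted over the list alone). In all, 246 of 9893 genes were at least 2-fold higher and 267 lower after OxPAPC, of which 216 and 232 passed limma, and 161 and 189 did so in size with undetected values at their bounds. Without background correction 41 and 85 reached 2-fold, and 33.3% of the genes past 2-fold were higher with median scaling against 48% here.

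Of the 24 lists 2 stood above and 10 below random lists between the compounds, and the BMP and TGF-β, Notch and immediate early lists were among those below. Of 14 BMP and TGF-β targets 6 were lower and 0 higher (median −0.74, percentile 0, 8 lower and 2 higher adjusted over the list alone), with SMAD7 at least 4.47-fold lower, ID2 at −2.08 ± 0.20 and ID3 at −1.10 ± 0.14. Of 11 Notch genes 4 were lower and 0 higher (median −0.44, percentile 0.37, 7 lower adjusted over the list alone), among them HEY1 at −1.90 ± 0.26, with a second probe at −0.02 and a mean of −0.96. The others were HES1 (at least 7.32-fold), DLL1 (−1.05 ± 0.32) and NRARP, which was at least 1.04-fold lower and so under 2-fold at its bound. Of 25 immediate early genes 6 were lower and 3 higher (median −0.19, percentile 0.2, 10 lower and 10 higher adjusted over the list alone), with IER5 at −2.46 ± 0.16, FOSB at −1.64 ± 0.25, MYC at 1.56 ± 0.14 and CCN1 at 1.58 ± 0.12. Of 10 PPAR targets ANGPTL4 (−2.31 ± 0.20), PDK4 (−1.92 ± 0.22) and PLIN2 (−1.04 ± 0.16, with a second probe at −0.94) were lower (median 0.05, percentile 66.9, 3 lower adjusted over the list alone). Of 30 endothelial genes APLN (−1.36 ± 0.16) and EGFL7 (−1.07 ± 0.19, with a second probe at −0.57) were lower and the flow-responsive KLF2 higher (1.24 ± 0.14; median −0.06, percentile 9.94, 6 lower and 4 higher adjusted over the list alone).

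Between the compounds 1 gene each passed in the ATF4, endoplasmic reticulum, S phase, p53 and haemostasis lists. In the ATF4 list SESN2 was lower after OxPAPC (−1.004 ± 0.25; median −0.27, percentile 0, 9 lower and 1 higher of 32 adjusted over the list alone), in the endoplasmic reticulum list HSPA5 was lower (−1.10 ± 0.14; median −0.18, percentile 0.07, 4 of 20 lower adjusted over the list alone), and in the S phase list FEN1 was lower (−1.003 ± 0.16, with a second probe at −0.60; median −0.42, percentile 0, 8 of 19 lower adjusted over the list alone). PLK2 was the p53 target that was higher (1.92 ± 0.19; median 0.44, percentile 100, 7 of 15 higher and 1 lower adjusted over the list alone), and F3 the haemostasis gene (1.23 ± 0.26; median −0.11, percentile 6.97, 1 higher and 2 lower of 12 adjusted over the list alone). Medians were −0.19 for 23 mitotic genes (percentile 1.37), −0.15 for 23 interferon-stimulated genes (5.51), −0.06 for 15 hypoxia genes (17.1), −0.08 for 27 proteasome genes (1.85) and −0.24 for 8 metallothionein genes (2.84), with 0 genes of these 5 lists past 2-fold. Adjusted over the list alone, these lists held 0, 2, 2, 0 and 0 higher and 0, 1, 4, 0 and 3 lower genes. Ribosomal and reference medians were −0.02 and −0.04, the former −0.24 with median scaling. The 5 smooth muscle, 4 leukocyte and 3 epithelial markers stayed under 2-fold, and of the lymphatic markers PROX1 was at least 2.55-fold lower and RELN at least 1.36-fold higher. Without background correction SESN2, EGFL7, IL1A, PLIN2, F3, FEN1, PROX1 and RELN were under 2-fold.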

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

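The test of HES1 and the counts of unnamed probes below were made after the values were seen.

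HES1, a transcriptional repressor downstream of Notch, was the 1 gene past 2-fold in opposite directions. HES1 was at least 3.13-fold lower than control after OxPAPC, where it was not detected, and measured 1.23 ± 0.28 after 15dPGJ2. The difference between the treatments was −3.14 with a limma adjusted p of 3.44e-11, but both values rest on a signal at background level after OxPAPC. Only the bound holds as a size, at least 7.32-fold lower after OxPAPC than after 15dPGJ2. Simulated unchanged arrays with a common control placed at most 1 gene in opposite directions, the number observed. Its difference from control was −0.91 and 0.88 without background correction, under 2-fold in both treatments.

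Probes without a gene name stood outside the comparisons by gene. Of these, 97 were at least 2-fold higher and 69 lower than in control among 3408 detected for OxPAPC, and 179 were higher and 99 lower among 3540 detected for 15dPGJ2. What they measure is not analysed here.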

How the results depend on the processing

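The rules that used the 2 arrays were chosen after the data were seen. Across the alternatives, 109 of the counts and correlations stayed within 1.5 times their value and 55 moved further, 537 list medians kept their side of the percentile limits, 18 crossed outward and 19 inward, and of the values of named genes 2928 kept their direction and side of the 2-fold rule, 16 rose past it, 61 fell short of it and 1 reversed. That was OAS1 after OxPAPC, at −0.37 as the mean of its probes. Counts are given as higher and lower for OxPAPC against control, 15dPGJ2 against control and OxPAPC against 15dPGJ2, then for both treatments. Without background correction they were 108 and 112, 182 and 134, 41 and 85, and 75 and 61 with 0 in opposite directions. With an offset of 50, which like the former shrinks the differences of dim genes, 184 and 225, 307 lower, 120 and 149, and 109 lower in both. With detection required in both groups, which removes genes, 247 lower, 269 and 310, 134 and 155, and 110 lower in both with 0 opposite. At 1.5-fold they were 821 and 1041, 1046 and 1328, 860 and 820, and 391 and 607 with 28 opposite, and at 3-fold 89 and 100, 161 and 126, 31 and 76, and 63 and 53 with 0 opposite. With 2-fold for every pairing of arrays they were 162 higher and, rounded, 2.0e+02 lower (361 in all), 257 and 275, 112 and 128, and 95 and 93 with 0 opposite. The authors' processed intensities gave 384 and 414 for OxPAPC against 15dPGJ2 and 5 opposite, and the mean of probes 2 opposite, and the cause was not tested. The lists below random lists after 15dPGJ2 numbered 3, in place of 5, with median scaling and with detection at p under 0.05. Median scaling put the share of higher genes at 55.7% for 15dPGJ2 against control (45.4% with quantile normalization) and 33.3% between the compounds (48%), and without background correction it was 57.6% and 32.5%. Signal over background limits the dim genes: 93 and 126, 152 and 196, and 112 and 112 of the 2-fold genes were not detected in their dimmer group. Of 121, 169 and 79 genes past 2-fold with several detected probes, all probes had the same direction in 112, 155 and 74. All probes also reached 2-fold in that direction in only 72, 91 and 40, so many of these calls depend on the probe chosen. The planned use of bead errors was not run because the table gives the SD of arrays, and leaving out each array was not run because only group means are given. No paired analysis was possible because the labels give 1 sample per group and the arrays carry no numbers.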

Other observations

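The groups in the following paragraphs, and the tests on heat shock genes and small RNAs, were chosen after the values were seen, while the test on the shared control was chosen before. Structural small RNAs separated the compounds. Of 13 detected vault, Y, 7SK, 7SL, 5S, U6-type, RNase P and RNase MRP RNAs, 9 rose after 15dPGJ2 (median 2.11) and 0 fell, while of 9 detected after OxPAPC or in control 0 rose. VTRNA2-1, RMRP, RNY4, RNY5 and VTRNA1-1 were not detected in control, so their rises have only bounds and the median is not a measured size. Of these only RNY5 was detected after OxPAPC, so the 2 sets differ in members. At the bounds, 14 of the 20 RNAs of this group and the U1-family group below were still at least 2-fold higher after 15dPGJ2. RNA5S9, a 5S ribosomal RNA gene, rose by 3.37 after 15dPGJ2 and differed by 0.12 after OxPAPC, RN7SK, which holds back elongation factor P-TEFb, by 1.83 and 0.08, and RNY1 by 2.45 and 0.52. RN7SL1 (0.02) and RNY3 (−0.51) did not rise after 15dPGJ2. Of the U1-family and other spliceosomal RNAs transcribed by RNA polymerase II, 5 of 7 rose after 15dPGJ2 and 4 of 6 after OxPAPC, and the U1 genes are near-identical copies. BRF2, a subunit of the initiation factor for RNA polymerase III at genes such as 7SK and U6, rose by 2.86 ± 0.18 after 15dPGJ2 and 1.96 ± 0.18 after OxPAPC.

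All 5 detected GIMAP genes, a cluster of immune-associated GTPases, fell after 15dPGJ2 (median −1.91) and 4 of the 5 after OxPAPC (median −2.18), among them GIMAP8 (−1.97 ± 0.16 and −2.95 ± 0.16) and GIMAP4 (−1.91 ± 0.14 and −2.18 ± 0.14). Of 5 detected targets of the aryl hydrocarbon receptor, 2 fell and 0 rose after each compound. These were CYP1A1 and CYP1B1. CYP1B1 fell by 3.81 after 15dPGJ2 and by 1.48 after OxPAPC, whereas TIPARP differed by 0.03 ± 0.13 after 15dPGJ2 and 0.97 ± 0.13 after OxPAPC. Endothelin 1 (EDN1), a vasoconstrictor peptide, fell by 1.48 ± 0.12 after 15dPGJ2 and 2.09 ± 0.12 after OxPAPC. The cytokine receptor IL7R rose by 3.05 ± 0.20 after 15dPGJ2 and differed by 0.21 ± 0.20 after OxPAPC, and MIR221, like MIR21 a microRNA gene, rose by 2.07 ± 0.26 after OxPAPC and differed by 0.65 ± 0.26 after 15dPGJ2.

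Genes changed in the same direction by both compounds numbered 349. Noise in the shared control would give at most 27 higher and 29 lower in the simulations, a sum of 56. When every pairing of arrays had to reach 2-fold, 188 genes passed. The simulated noise was normal, with its size taken from the median absolute deviation, and put about 197 genes past 2-fold per treatment. Noise of that size does not account for all of the 349 genes, but larger noise in single genes was not simulated. A shift common to both control arrays, such as a culture difference, stays open, as does any common effect of handling. That the compounds share targets through reactive thiols may be a further explanation, which the design did not test because the doses differ and no unreactive analogue was measured.

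The rise of heat shock genes extended past the HSP70 family. If hybridisation between near-identical HSP70 genes were the source of the whole list's rise, other members would not move. Yet 15 of 20 detected members outside that family were at least 2-fold higher after 15dPGJ2 and 9 of 20 after OxPAPC. Some of these, such as DNAJB1, had already been seen among the largest rises. How far such hybridisation adds to the values of the HSP70 genes themselves stays open. With median scaling in place of quantile normalization the list's median after 15dPGJ2 was 2.01, within 1.71 to 2.01 over the normalizations. Median scaling moved the median of all counted genes only from −0.037 to 0.035, so it could hardly have removed the rise. The list's rise did not depend on the choice among these normalizations, and an error common to them was not tested. No biological explanation was tested.

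The rise of structural small RNAs after 15dPGJ2 could come from a higher yield of all short RNAs in that sample. If that yield did not depend on length, it would raise small nucleolar RNAs by as much. The median of 63 detected small nucleolar RNAs, of which 49 were detected in control, was 0.0201. With RNAs not detected in a group at their bounds, it was 0.37 for 33 box C/D RNAs (95% bootstrap interval −0.02 to 0.59) and −0.14 for 30 box H/ACA RNAs (−0.33 to 0.09), against 1.70 (1.10 to 3.01) for the 20 RNAs of the pattern, of which 6 were not detected in control, and 1.34 (0.69 to 2.45) for the 16 outside the U1 family. Without bounds the pattern's median was 2.28, and 2.35 with median scaling, within 1.37 to 2.85 over the normalizations. The rise did not depend on the choice among these normalizations, and an error common to them was not tested. Small nucleolar RNAs as a group did not rise by as much as the RNAs of the pattern. The pattern was grouped after large rises among its members were seen, so this gap may be overstated and is not an independent test of yield. The intervals describe the spread between RNAs, not between samples. A smaller rise in yield, in the direction of the box C/D RNAs, stays open. So does a yield that depends on length, because the groups were not matched on length. Polyadenylation of these RNAs was not measured and no biological explanation was tested.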
